A study of Carassius gibelio with 6 samples.

How the data were processed

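Gill RNA from control and deltamethrin-exposed juvenile gibel carp was sequenced as 6 poly-A libraries, 3 per group, and groups were taken from the sample labels. Per the submitters' processing notes, the tools were CASAVA, HISAT2 2.0.5 for alignment and featureCounts 1.5.0-p3 for counting. The genome build and the annotation behind the gene identifiers are not named in the sources used here. Coordinates and gene copies are therefore those of the deposited table, with no build named. Whether these gene models were made from gibel carp was not checked. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled for depth), per the file headers, with 68370 gene entries, of which 62113 carry Ensembl identifiers and 6257 other identifiers. Symbols, descriptions, lengths and positions come from that table, and 42786 entries have a symbol. A reference table of gene names matched 0 of these identifiers and was not used. In 14490 entries all libraries were at 0, and 18 lines held no values.

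The deposited FPKM multiplied by gene length gave whole reads for 100% of values in each library, within a tolerance of 0.001 reads, after dividing by the step of that library. The totals were 8861533 to 10737319 reads per library. The depth divisor in each library was 1 constant times the median-of-ratios size factor, so the deposited values were already scaled by size factors. A median-of-ratios scaling, listed as an alternative, therefore applied the same constant to every library and tests nothing about scaling. Because the values are FPKM, no count model was used for the reported results. No pair of libraries held identical values. The labels do not state whether the library kit kept strand, so reads of overlapping antisense genes, and of near-identical copies, cannot be told apart with certainty.

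Values were tested as log2(FPKM + 1) in genes with a mean of at least 1 FPKM over the 6 libraries. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trended prior), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The pseudocount of 1 makes fold changes of low genes too small. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over 34 lists. Counts of members past the threshold are given over all genes and adjusted over the list alone. With an estimated correlation, 0 of the 17 called lists kept the call. Descriptions shared by at least 10 tested genes formed 329 families, tested in the same way. Single values per library were compared with exact permutation tests. Figures and summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

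The test, the lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule took the 10 largest changes in each direction among genes past the threshold, without overlap between groups and with a symbol or description, up to 4 members of each list with the smallest p, and the tested copies of 12 genes chosen for the exposure. Of those 12 genes, 1 is not reported here. The text patterns that found the copies of those 12 genes were written and amended after values had been seen. Words removed from descriptions to form families were also adjusted after a first result, to follow the written rule. Alternatives covered the pseudocount, the filter, scaling, the prior variance, weights, a replicate block, merged copies, limma voom on the recovered reads, other list tests, and leaving out each library. Added after seeing the data were scaling to total reads, the mitochondrial share of reads as a covariate, and leaving out deltamethrin libraries 1 and 3, which had the highest mitochondrial shares.

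The tests were tried on simulated data for this comparison over 29766 genes, with 200 genes seeded. The test called 0 of 50 genes seeded at 2-fold, 27 of 50 at 4-fold, 39 of 50 at 8-fold and 43 of 50 at 16-fold, all 109 in the right direction, with 9 false calls (7.63% of calls). With none seeded it made 1 call. Both simulated groups were given the same spread, while the real exposed libraries differed from one another more than the controls did. These rates of calls and false calls therefore hold only for groups of equal spread. A seeded list of 60 genes at 2-fold had a camera adjusted p of 2.25e-39, and 0 of 30 random lists were called. Each simulated gene was drawn independently of the others. The simulation therefore cannot show how often the list test makes false calls when the genes of a list vary together.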

Results

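RNA was profiled in gill tissue of juvenile gibel carp (Carassius gibelio), a polyploid fish related to goldfish, after exposure to deltamethrin. Deltamethrin is a pyrethroid insecticide that holds voltage-gated sodium channels open. The gill is the organ of gas exchange, ion transport and ammonia excretion, and it is in direct contact with the dissolved compound. The fish weighed 8.8 ± 1.0 g. The study design names 4 concentrations, from a lowest of 0.61 µg/L to a highest of 4.88 µg/L, and which of them the sequenced fish received is not given in the sources used here. There were 6 poly-A libraries, 3 from control gills and 3 from gills taken after 24 h of deltamethrin. Reads assigned to genes numbered 10737319, 10437208 and 10370001 in control libraries 1 to 3, and 9397487, 10633002 and 8861533 in deltamethrin libraries 1 to 3. The labels do not say whether each library came from a separate fish or a pool, so p-values measure the spread between these libraries, which may in part be technical.

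The comparison asked which transcripts differed in the gill after 24 h of deltamethrin. By the list test with its preset correlation, glucocorticoid-responsive and immediate early genes were higher in the exposed gills, and interferon and antigen presentation genes were lower. With an estimated correlation these lists were not past the threshold (adjusted p = 0.0725, 0.297, 0.0725 and 0.379 in that order). The nucleotidase gene nt5c2l1 went from 1.56 ± 0.779 FPKM in controls to 112 ± 65.6 after exposure (mean ± SD, n = 3 libraries per group, as in all pairs of levels that follow). The macrophage gene mpeg1.2, which encodes a pore-forming protein of phagocytes, went from 50.5 ± 14.9 to 1.20 ± 0.713 FPKM. Of 29766 genes tested, 1107 changed at a limma adjusted p under 0.05, of which 582 were higher and 525 lower. Of these, 1105 changed at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. All 1107 had no overlap between groups, and so did 8175 genes in all (27.5%, against 10% by chance). With reads scaled to each library's total, an alternative chosen after seeing the data, the split became 493 higher and 684 lower of 1177, and the median log2 change of all genes was -0.15 instead of -0.04. The count was 148, 144 and 83 without control library 1, 2 or 3, and 374, 5860 and 734 without deltamethrin library 1, 2 or 3.

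The 10 named genes with the largest rises were led by nt5c2l1 and tgm8. The 5'-nucleotidase gene nt5c2l1 (chromosome 35, 5812352 to 5822473) had a log2 change of 5.27 (SE 0.53, limma adjusted p = 0.00513). A pair of copies of pnp5a, which encodes purine nucleoside phosphorylase, rose from 4.17 ± 0.835 to 96.7 ± 20.9 FPKM (chromosome 7, 10259894 to 10264046) and from 1.88 ± 0.928 to 52.8 ± 14.9 FPKM (chromosome 7, 2304832 to 2307566). The adjusted p was 0.00184 for each copy. The hypoxanthine phosphoribosyltransferase gene hprt1l rose from 0.704 ± 0.476 to 38.7 ± 25.6 FPKM. Also among these 10 were the transglutaminase gene tgm8 (log2 change 4.84), the calcium-binding protein gene cabp4 (4.42), and zgc:86709, described as a cardiac alpha actin (4.22). The others were igfbp1a, a binding protein of insulin-like growth factors (4.20), ramp2, a partner of the calcitonin receptor-like receptor (4.06), and the inositol phosphate kinase gene ipmkb (4.02). The highest adjusted p among the 10 was 0.0117.

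The 10 genes with the largest falls included a pair of chemokine gene copies and an ammonium transporter gene. After mpeg1.2 (chromosome 8, 10250709 to 10253623; log2 change -4.56, SE 0.35, limma adjusted p = 0.00184) came zgc:171592, described as chymotrypsin A (-4.49). A pair of copies of the chemokine gene ccl19b fell, from 58.1 ± 34.7 to 2.13 ± 2.55 FPKM and from 42.8 ± 21.1 to 1.41 ± 1.58 FPKM. The gene irg1l, which encodes the enzyme that makes itaconate in activated macrophages, fell from 16.8 ± 9.83 to 0.148 ± 0.176 FPKM. The Rh-type ammonium transporter gene rhcga fell from 17.3 ± 7.65 to 0.169 ± 0.293 FPKM (chromosome 32, 27164050 to 27168724). The sialic acid synthase gene nansb had a log2 change of -4.37, the G protein subunit gene gng13a -4.29, and the receptor kinase gene grk5 -3.81. With each library left out in turn, nansb was past the threshold in 2 of 6 fits and gng13a in 1 of 6. The levels of gng13a were 0, 11.6 and 0 FPKM in deltamethrin libraries 1 to 3. An unnamed locus with a ubiquitin domain had -3.80. Of these 20 genes, 10 stayed past the threshold whichever library was left out. The number past it was 17, 16 and 10 without control library 1, 2 or 3, and 17, 20 and 18 without deltamethrin library 1, 2 or 3. For all 132 named genes that changed in the full comparison, those numbers were 46, 45 and 31, and 77, 132 and 102. With gene copies merged, 27 of the 132 were no longer past the threshold, rhcga among them (-3.27, adjusted p = 0.0715).

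**Figure D1:**
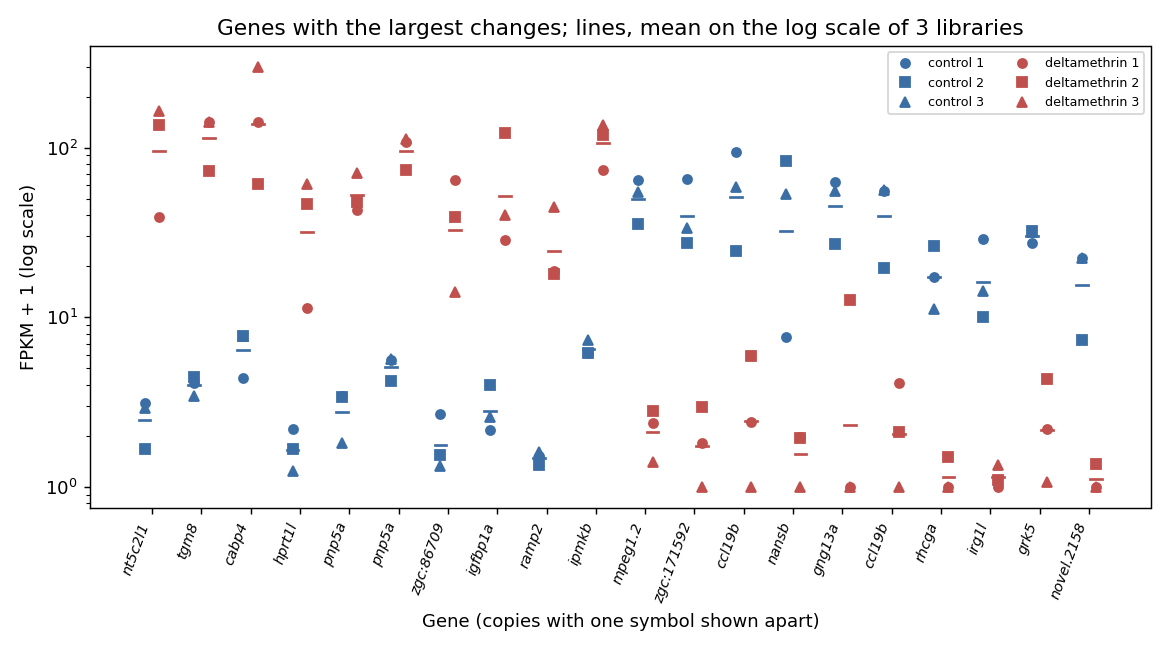
FPKM + 1 on a log axis for the 20 named genes with the largest rises and falls, with 1 point per library (blue, control; red, deltamethrin) and a line at the mean on the log scale of each group of 3. In each gene the control and deltamethrin points do not overlap; nt5c2l1 averaged 1.56 FPKM in controls and 112 after exposure, and mpeg1.2 averaged 50.5 and 1.20.

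Members of the glucocorticoid, immediate early and clock lists were among the genes that rose. Of 49 glucocorticoid-responsive genes tested, 20 rose, 1 fell and 28 did not pass; adjusted over the list alone, 29 rose and 2 fell. Their median log2 change was 1.14 (camera adjusted p = 9.84e-12; adjusted p = 0.0725 with an estimated correlation). SGK1, a kinase that regulates ion channels, rose from 5.05 ± 0.626 to 52.4 ± 16.2 FPKM, and the glutamine synthetase gene glula rose from 73.4 ± 0.746 to 323 ± 57.8 FPKM. The phosphatase gene dusp1, which switches off MAP kinases, had a log2 change of 2.42 (SE 0.27). Of 141 immediate early genes, 31 rose, 2 fell and 108 did not pass, or 49 and 6 adjusted over the list alone. Their median was 0.49 (camera adjusted p = 1.37e-09; adjusted p = 0.297 with an estimated correlation). The 3 named copies of the AP-1 subunit gene junbb rose, the most abundant of them from 10.4 ± 2.82 to 89.2 ± 20.1 FPKM, and fosb rose from 0.688 ± 0.193 to 8.14 ± 0.548 FPKM. Of 81 circadian clock genes, 7 rose, 0 fell and 74 did not pass, or 14 and 1 adjusted over the list alone. Their median was 0.11 (camera adjusted p = 0.00979; adjusted p = 0.379 with an estimated correlation), and it was below 0 with no filter (-0.02) and with total-read scaling (-0.00). The members that led were the bZIP repressor genes nfil3-6 (log2 change 3.01) and nfil3-3 (2.28), then bhlhe41 (1.63) and nr1d2a (1.29), which encode repressors within the clock loop. The clock list was no longer past the threshold without control library 3 (adjusted p = 0.0506) or deltamethrin library 2 (0.105), with no filter (0.0716), with array weights (0.0690) or with gene copies merged (0.170).

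Some glycolysis and chaperone genes also rose. Of 153 glycolysis and hypoxia genes, 17 rose, 0 fell and 136 did not pass, or 29 and 2 adjusted over the list alone. The median log2 change was 0.30 (camera adjusted p = 1.10e-05; adjusted p = 0.379 with an estimated correlation). Copies of pdk2b, which encodes a kinase that inhibits pyruvate dehydrogenase, rose from 16.8 ± 1.49 to 122 ± 6.59 FPKM and from 5.25 ± 2.53 to 57.2 ± 10.6 FPKM. The gene pfkfb3, which encodes an enzyme that makes an activator of glycolysis, rose from 6.83 ± 1.19 to 29.4 ± 0.253 FPKM. Of 113 heat shock proteins and chaperones, 4 rose, 1 fell and 108 did not pass, or 9 and 2 adjusted over the list alone. The median was 0.31 (camera adjusted p = 0.00257; adjusted p = 0.444 with an estimated correlation). The small heat shock protein genes hspb6 (59.7 ± 5.11 to 218 ± 103 FPKM) and hspb11 (3.82 ± 1.86 to 30.9 ± 21.9 FPKM) rose, as did the DnaJ gene zgc:122979 and a gene described as heat shock factor 1 (log2 changes 2.03 and 1.37).

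Some matrix remodelling and endothelial genes rose as well. Of 156 collagen and matrix remodelling genes, 17 rose, 3 fell and 136 did not pass, or 30 and 9 adjusted over the list alone. The median log2 change was 0.27 (camera adjusted p = 0.00131; adjusted p = 0.444 with an estimated correlation). The leading members were not collagens. Copies of adamts1, a secreted protease, had log2 changes of 3.06 and 1.86, the matricellular protein gene ccn1 had 2.26, and postnb (periostin) fell from 16.4 ± 1.80 to 4.90 ± 0.797 FPKM. The list lost its call with no filter (camera adjusted p = 0.0859) and with the mitochondrial share of reads as a covariate (0.0572). Without deltamethrin libraries 1 and 3, which had the highest mitochondrial shares, its median was 0.12. That fit leaves 1 exposed library. The covariate and this omission were both chosen after seeing the data. Of 56 endothelial and pillar cell markers, 10 rose, 2 fell and 44 did not pass, or 21 and 2 adjusted over the list alone. Pillar cells line the blood spaces of the gill lamellae. The median of these markers was 0.81 (camera adjusted p = 7.70e-10; adjusted p = 0.297 with an estimated correlation). It was 0.49 with the mitochondrial share as a covariate and 0.44 without deltamethrin libraries 1 and 3. By library it was 0.79, 0.44 and 1.25 in deltamethrin libraries 1 to 3. The hyaluronan receptor gene lyve1a rose from 8.75 ± 3.52 to 147 ± 30.2 FPKM. The endothelin receptor genes EDNRA and ednraa rose (log2 changes 2.08 and 1.44), as did the endothelial adhesion gene esama (1.82).

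The interferon and antigen presentation lists held genes that fell in the exposed gills. Of 106 interferon and antiviral genes, 17 fell, 1 rose and 88 did not pass, or 38 and 2 adjusted over the list alone. The median log2 change was -0.79 (camera adjusted p = 1.47e-12; adjusted p = 0.0725 with an estimated correlation). The ubiquitin-like gene isg15 fell from 5.95 ± 2.07 to 0.0940 ± 0.163 FPKM, the antiviral GTPase gene mxa from 11.2 ± 4.43 to 0.868 ± 0.591 FPKM, and the fish antiviral gene gig2p from 9.78 ± 2.34 to 1.51 ± 0.456 FPKM. The gene stat1b, a transcription factor of the interferon pathway, had a log2 change of -1.80, and -0.75 with its copies merged (adjusted p = 0.158). Of 84 antigen presentation genes, 9 fell, 0 rose and 75 did not pass, or 25 and 0 adjusted over the list alone. Their median was -0.60 (camera adjusted p = 3.79e-10; adjusted p = 0.379 with an estimated correlation), and -0.36 with the mitochondrial share as covariate. By library it was -0.72, -0.32 and -0.82 after exposure and 0.17, -0.22 and 0.07 in controls. The tapasin genes tapbpl and tapbp.1, whose products load peptide onto MHC class I, had log2 changes of -2.65 and -1.94. Pan-leukocyte genes, chosen after seeing the data, also had a median of -0.60 (43 tested). The costimulatory receptor gene cd40 fell from 15.5 ± 2.22 to 3.44 ± 0.666 FPKM.

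A few immune cell markers also fell. Of 45 T cell markers, 1 fell, 0 rose and 44 did not pass, with the same counts adjusted over the list alone. The median log2 change was -0.80 (camera adjusted p = 3.19e-06; adjusted p = 0.444 with an estimated correlation). The member that fell was sh2d1aa, a signalling adaptor of lymphocytes (10.8 ± 1.27 to 2.67 ± 0.785 FPKM). Granzyme K (-1.68) and prf1.3, a perforin (-1.17), had adjusted p of 0.0872 and 0.0860. Of 45 macrophage markers, 4 fell, 0 rose and 41 did not pass, or 9 and 1 adjusted over the list alone. The median was -0.48 (camera adjusted p = 0.00405; adjusted p = 0.579 with an estimated correlation). Besides mpeg1.2, the lysosomal protease gene ctsz fell from 19.3 ± 1.19 to 7.15 ± 2.78 FPKM. With copies merged neither sh2d1aa (-1.31, adjusted p = 0.142) nor ctsz (-0.90, adjusted p = 0.125) was past the threshold. The same held for the other macrophage markers that fell besides mpeg1.2. They are described as microfibril-associated glycoprotein 4 (-0.13, adjusted p = 0.822) and scavenger receptor M130 (-1.47, adjusted p = 0.0716). Both lists lost their call with the mitochondrial share as a covariate (camera adjusted p = 0.0572 for T cell markers and 0.148 for macrophage markers). The macrophage list also lost it with no filter (0.0561). Without deltamethrin libraries 1 and 3, which leaves 1 exposed library, the medians were -0.24 for T cell and -0.21 for macrophage markers. Of 192 pattern recognition and NF-kB genes, 6 fell, 1 rose and 185 did not pass, with the same counts adjusted over the list alone. Their median was -0.22 (camera adjusted p = 0.00870; adjusted p = 0.379 with an estimated correlation). Those that fell included genes described as NLRP-type receptors and NLRC5, while tlr5a, a flagellin receptor, rose from 0.0910 ± 0.0565 to 3.02 ± 1.42 FPKM. With copies merged the NLRP-type genes named by the rule were not past the threshold (adjusted p = 0.0834 and 0.0969). The call of the list was lost when members were matched by symbol only (adjusted p = 0.841), with copies merged (0.101) and with a minimum mean of 5 FPKM (0.191).

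Inflammatory genes went both ways. Of 108 inflammatory cytokine and chemokine genes, 10 rose, 13 fell and 85 did not pass, or 18 and 27 adjusted over the list alone, and the list as a whole was not past the threshold (median log2 change -0.17, camera adjusted p = 0.277). The inducible nitric oxide synthase gene nos2a fell from 13.7 ± 8.03 to 0.189 ± 0.166 FPKM. The prostaglandin synthase gene ptgs2a rose from 24.1 ± 3.21 to 80.8 ± 5.24 FPKM, and the transcription factor gene cebpb from 82.7 ± 10.3 to 346 ± 84.5 FPKM. Among 59 neutrophil and granulocyte markers, 1 rose, 2 fell and 56 did not pass, or 1 and 5 adjusted over the list alone (median -0.26, camera adjusted p = 0.0918). The lipoxygenase gene alox5a and the protease gene npsn fell (log2 changes -1.32 and -1.48), while noxa1, described as a neutrophil cytosolic factor, rose (1.43). With copies merged alox5a had -0.90 (adjusted p = 0.0617). Without control library 2, the cytokine list had an adjusted p of 0.0358 and the neutrophil list 0.0292. Among 44 B cell markers, 1 rose, 1 fell and 42 did not pass, or 1 and 4 adjusted over the list alone (median -0.24, camera adjusted p = 0.322, and 0.00798 with a minimum mean of 5 FPKM). A gene with the symbol cd22 rose (2.02) and swap70a fell (-1.46). Among 72 complement and coagulation genes, 4 rose, 0 fell and 68 did not pass, or 6 and 2 adjusted over the list alone (median 0.08, camera adjusted p = 0.321). These included F3, the tissue factor that starts clotting (log2 change 2.04), the terminal complement gene c7b (1.06 ± 0.342 to 21.6 ± 13.5 FPKM) and vwf (5.85 ± 1.81 to 25.2 ± 13.2 FPKM).

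The cell cycle, ribosomal and oxidative phosphorylation lists held a few genes that fell. Of 164 cell cycle genes, 6 fell, 0 rose and 158 did not pass, with the same counts adjusted over the list alone. The median log2 change was -0.46 (camera adjusted p = 7.12e-08; adjusted p = 0.393 with an estimated correlation). The replication clamp gene pcna fell from 26.9 ± 9.79 to 4.28 ± 3.03 FPKM and the helicase subunit gene mcm2 from 6.60 ± 1.83 to 0.805 ± 0.855 FPKM. The clamp loader gene rfc3 (-1.39) and the polymerase subunit gene pole4 (-1.26) also fell. Of 367 ribosomal protein genes, 4 fell, 0 rose and 363 did not pass, and 0 passed adjusted over the list alone (median -0.32, camera adjusted p = 8.85e-04; adjusted p = 0.741 with an estimated correlation). Of the members that fell, mrpl11 and mrps15 encode parts of the mitochondrial ribosome, and rps27.1 (130 ± 75.3 to 14.8 ± 2.09 FPKM) a part of the cytosolic one. Of 225 genes of mitochondrial oxidative phosphorylation, 1 fell, 0 rose and 224 did not pass, and 0 passed adjusted over the list alone (median -0.38, camera adjusted p = 3.43e-04; adjusted p = 0.678 with an estimated correlation). The member that fell was the complex III subunit gene uqcr10 (log2 change -2.15). With copies merged the log2 changes were -0.57 for rps27.1, -0.45 for uqcr10, -0.79 for mrpl11, -0.47 for mrps15, -0.75 for rfc3 and -0.47 for pole4, and none of these 6 was past the threshold (adjusted p from 0.106 to 0.392). The share of reads on mitochondrial genes was 7.84%, 2.90% and 10.7% in deltamethrin libraries 1 to 3 and 3.16%, 2.71% and 3.20% in the controls. With this share as a covariate the ribosomal and oxidative phosphorylation lists had camera adjusted p of 0.521 and 0.611. Without deltamethrin libraries 1 and 3, which leaves 1 exposed library, their medians were -0.14 and -0.08. The ribosomal list was also not past the threshold without control library 3 (0.0596), without deltamethrin library 3 (0.201) or with array weights (0.0525).

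Some erythrocyte and skeletal muscle markers rose with exposure, and the cartilage and thymocyte lists were not past the threshold. Of 38 erythrocyte markers, 10 rose, 1 fell and 27 did not pass, or 17 and 4 adjusted over the list alone (median log2 change 0.94, camera adjusted p = 1.39e-05; adjusted p = 0.327 with an estimated correlation). The list holds nt5c2l1, a nucleotidase gene, whose other copies rose from 0.790 ± 0.121 to 21.6 ± 3.39 FPKM and from 0.625 ± 0.271 to 24.0 ± 7.71 FPKM. The globin gene zgc:163057 rose from 5.44 ± 0.816 to 64.9 ± 27.7 FPKM. Summed hemoglobin levels were 3050, 3358 and 1594 FPKM in the controls and 15527, 9647 and 2009 FPKM in deltamethrin libraries 1 to 3. The two-sided exact permutation p for this sum was 0.3, and 3 against 3 cannot go below 0.1. Of 142 skeletal muscle markers, 4 rose, 0 fell and 138 did not pass, with the same counts adjusted over the list alone (median 0.34, camera adjusted p = 2.20e-05; adjusted p = 0.486 with an estimated correlation). The list median was 0.72, 0.58 and -0.14 in deltamethrin libraries 1 to 3, so that library 3 lay below the control mean. The median change was 0.75 with the mitochondrial share as a covariate and 0.61 without deltamethrin libraries 1 and 3. Besides zgc:86709, the members that rose were acta1a (1.46 ± 0.160 to 7.67 ± 2.69 FPKM), myoz3a and a fast myosin heavy chain gene (log2 changes 1.70 and 1.76). Among 34 cartilage and bone markers, 3 rose, 1 fell and 30 did not pass, or 5 and 2 adjusted over the list alone (median 0.19, camera adjusted p = 0.321). Those that rose were both copies of the hedgehog ligand gene ihha (log2 changes 2.32 and 2.38) and col10a1b (1.98), and ucmaa fell (-1.46). With copies merged col10a1b (adjusted p = 0.0527) and ucmaa (-0.61, adjusted p = 0.298) were not past the threshold. Of 19 thymocyte markers 0 passed, and 1 was higher adjusted over the list alone (median -0.00, camera adjusted p = 0.510). The chemokine receptor gene ccr9a had 56.8 ± 1.68 and 174 ± 90.0 FPKM (adjusted p = 0.0540).

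**Figure D2:**
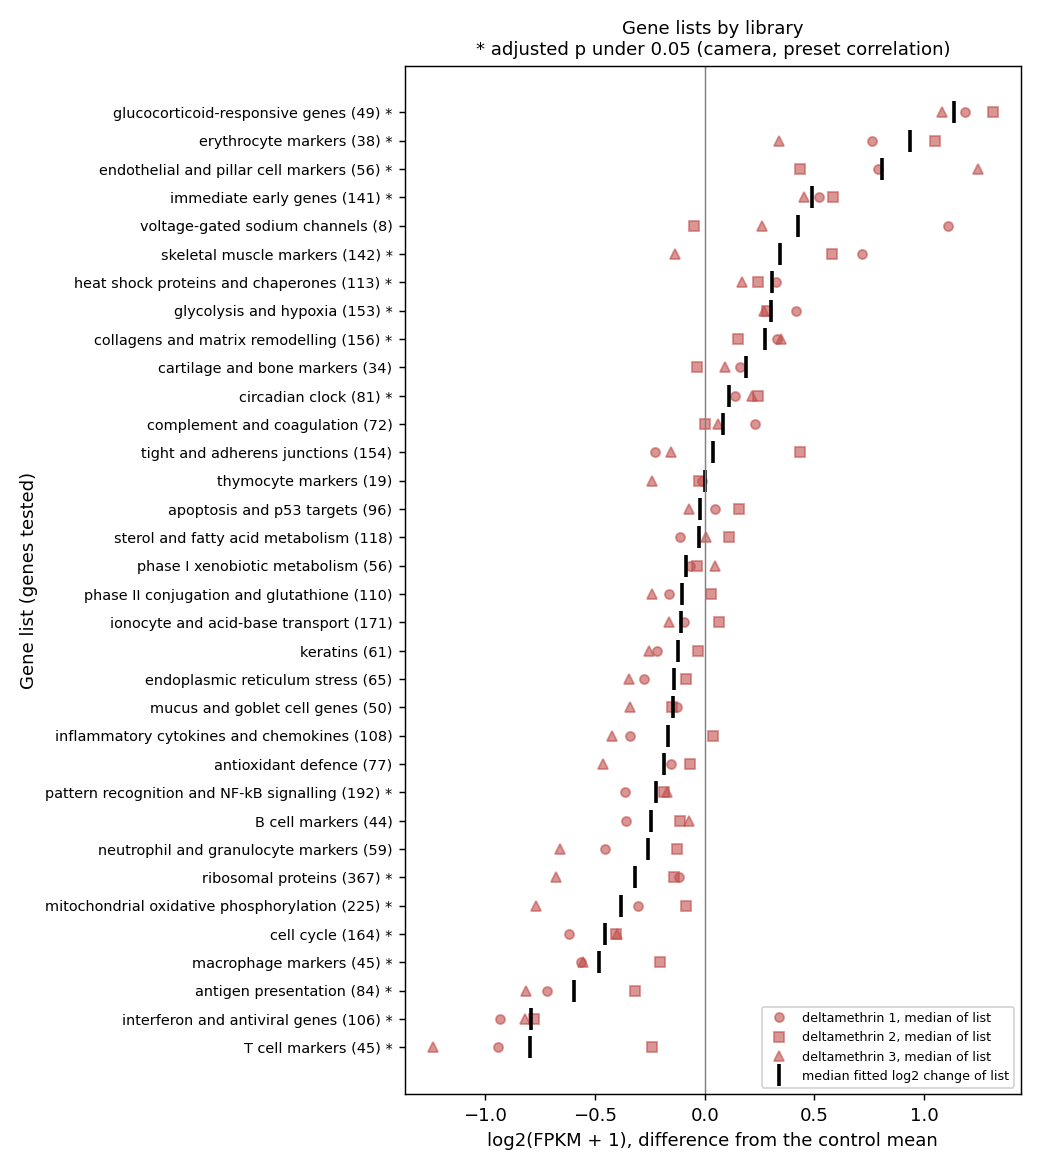
Median difference from the control mean on the log2(FPKM + 1) scale for the tested members of each of 34 gene lists, with 1 red point per deltamethrin library and a black line at the median fitted log2 change. Numbers in brackets are genes tested, and a star marks a camera adjusted p under 0.05 with the preset correlation; the glucocorticoid-responsive list lies highest (1.14) and the T cell list lowest (-0.80).

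The gill epithelium showed changes in single genes, while its lists were not past the threshold. Of 171 ionocyte and acid-base transport genes, 4 rose, 6 fell and 161 did not pass, or 6 and 8 adjusted over the list alone (median log2 change -0.11, camera adjusted p = 0.933). The ammonia channel gene rhbg fell from 297 ± 22.5 to 35.5 ± 28.2 FPKM along with rhcga, and a carbonic anhydrase 4 gene fell from 72.9 ± 13.6 to 7.32 ± 6.98 FPKM. The anion transporter gene slc26a5 rose (1.30). Of 61 keratin-list genes, 1 rose, 5 fell and 55 did not pass, or 3 and 13 adjusted over the list alone (median -0.12, camera adjusted p = 0.321). The keratin genes krt1-19d (26.7 ± 11.6 to 4.38 ± 0.437 FPKM), krt99 (-1.62) and krt98 (-2.50) fell. With copies merged the krt98 change had the opposite sign, 0.60 (adjusted p = 0.518), and krt1-19d had -0.37 (adjusted p = 0.346). The member that rose was tgm1 (2.03), an enzyme that crosslinks the cornified envelope. Of 154 tight and adherens junction genes, 2 rose, 2 fell and 150 did not pass, with the same counts adjusted over the list alone (median 0.04, camera adjusted p = 0.411). The desmosomal gene dsc2l rose from 8.15 ± 3.03 to 49.7 ± 24.6 FPKM and cldn5b, a claudin, from 1.15 ± 0.617 to 11.8 ± 8.04 FPKM, while cgnb (cingulin) and dspb (desmoplakin) fell (-2.20 and -1.59). With copies merged cgnb had -0.60 (adjusted p = 0.139) and cldn5b 1.48 (adjusted p = 0.158). The junction list median was -0.23, 0.44 and -0.16 in deltamethrin libraries 1 to 3, so that only library 2 lay above the control mean. This list was higher without deltamethrin library 1 (camera adjusted p = 0.0230) and with the mitochondrial share as a covariate (1.23e-04). Without deltamethrin libraries 1 and 3, which leaves only library 2 in the exposed group, its median was 0.44. Of 50 mucus and goblet cell genes, 2 rose, 1 fell and 47 did not pass, or 4 and 3 adjusted over the list alone (median -0.14, camera adjusted p = 0.643). The lectin gene itln3 rose from 0.358 ± 0.149 to 12.7 ± 6.68 FPKM, st3gal1l rose (2.81), and a Mucin-2 gene fell from 22.6 ± 6.03 to 5.35 ± 2.62 FPKM, though its change was -0.78 with copies merged (adjusted p = 0.648).

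Lists of chemical defence and cell damage were not past the threshold either. Of 56 phase I genes, 1 rose, 1 fell and 54 did not pass, with the same counts adjusted over the list alone (median log2 change -0.08 against an upward camera direction, adjusted p = 0.722). The P450 reductase gene porb rose from 8.70 ± 0.973 to 28.8 ± 5.74 FPKM, and a flavin monooxygenase gene, zgc:77439, fell (-1.54). With copies merged porb had 0.63 (adjusted p = 0.140). Of 110 phase II genes, 5 fell, 0 rose and the others did not pass, or 6 and 0 adjusted over the list alone (median -0.10, camera adjusted p = 0.322, and 0.0135 with a minimum mean of 5 FPKM). The glutathione transferase genes gstm.3 (63.0 ± 17.4 to 17.2 ± 4.94 FPKM), gstr (-1.37) and gstt1b (-1.32) fell, the last not with copies merged (adjusted p = 0.0581). Of 77 antioxidant genes, 1 rose, 3 fell and 73 did not pass, or 6 and 8 adjusted over the list alone (median -0.18, camera adjusted p = 0.287). The peroxiredoxin genes prdx4, prdx6 and prdx2 fell (-1.34, -1.65 and -1.27). Of 65 endoplasmic reticulum stress genes, 5 rose, 6 fell and 54 did not pass, or 5 and 8 adjusted over the list alone (median -0.14, camera adjusted p = 0.322). Both named copies of chac1, a glutathione-degrading enzyme, rose (log2 changes 2.33 and 2.33), as did trib3 (1.82), and the disulfide isomerase gene pdia4 fell (-1.83). Of 96 apoptosis and p53 genes, 10 rose, 4 fell and 82 did not pass, or 18 and 7 adjusted over the list alone (median -0.02 against an upward camera direction, adjusted p = 0.322). Copies of gadd45ba rose (2.07 and 1.84), as did mdm2, the ubiquitin ligase of p53 (log2 change 1.64). Of 118 sterol and fatty acid genes, 1 rose, 0 fell and 117 did not pass, with the same counts adjusted over the list alone (median -0.03 against an upward camera direction, adjusted p = 0.322). It was the fatty acid elongase gene elovl1b (26.9 ± 3.47 to 135 ± 68.7 FPKM).

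The list of voltage-gated sodium channels, the channels that deltamethrin acts on, had 8 tested genes, with auxiliary subunit genes such as scn3b among them. Of these genes, 0 passed over all genes or adjusted over the list alone (median log2 change 0.43, camera adjusted p = 0.376). Their levels were low, with scn4ab at 6.85 ± 1.95 and 10.3 ± 3.56 FPKM and scn3b at 2.09 ± 0.569 and 8.17 ± 8.23 FPKM.

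Among 12 genes chosen for the exposure and the tissue, il1b, il6, cxcl8 and hmox1 held changed copies. Both tested il1b copies rose (7.12 ± 2.04 to 40.6 ± 14.2 FPKM and 4.73 ± 0.866 to 22.5 ± 9.01 FPKM), with limma adjusted p of 0.0106 and 0.0194. Of 2 il6 copies, 1 rose (5.91 ± 3.05 to 17.4 ± 2.37 FPKM, adjusted p = 0.0474) and the other did not pass (adjusted p = 0.0903). Of 6 cxcl8 copies, 1 fell (log2 change -1.34, adjusted p = 0.0371), and the others ranged up to 0.51. Of 3 hmox1 copies, 1 rose (log2 change 2.62, adjusted p = 0.0155). The single tested tnf copy, which carries the symbol tnfb and not tnfa, had a log2 change of -1.10 (limma adjusted p = 0.193). The cyp1a copies had 1.31 and -0.79 (0.0623 and 0.236). The smallest adjusted p was 0.127 over 2 il10 copies, 0.136 over 4 tgfb1 copies, 0.0625 over 2 hsp70 copies, 0.201 over 3 sod1 copies and 0.0924 over 2 cat copies. Copies of a gene in this polyploid fish can share reads, so values of single copies are uncertain.

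The exposed libraries differed from one another more than the controls did. Control libraries correlated with one another across genes at r from 0.951 to 0.955. Deltamethrin library 1 correlated with the controls at 0.823 to 0.837, library 2 at 0.884 to 0.899 and library 3 at 0.783 to 0.801. Among themselves the deltamethrin libraries correlated at 0.819 to 0.873. The first principal component held 50.7% of the variance, with scores of -64.6, -57.7 and -56.1 for the controls and 76.2, -13.4 and 115 for deltamethrin libraries 1 to 3. Genes with a value above 0 numbered 45952, 46312 and 43888 in the controls and 39289, 45981 and 34917 in the deltamethrin libraries. The two-sided exact permutation p between groups was 0.3 for this number and 0.3 for the mitochondrial share, and it cannot go below 0.1 with 3 against 3. Leaving out deltamethrin libraries 1 and 3, an alternative chosen after seeing the data, left 1 exposed library. Its spread cannot be measured, so no count of changed genes is given for that fit. The median log2 change of all genes was then -0.03. With the mitochondrial share as a covariate, also chosen after seeing the data, 461 genes changed, 337 of them among the 1107.

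**Figure D3:**
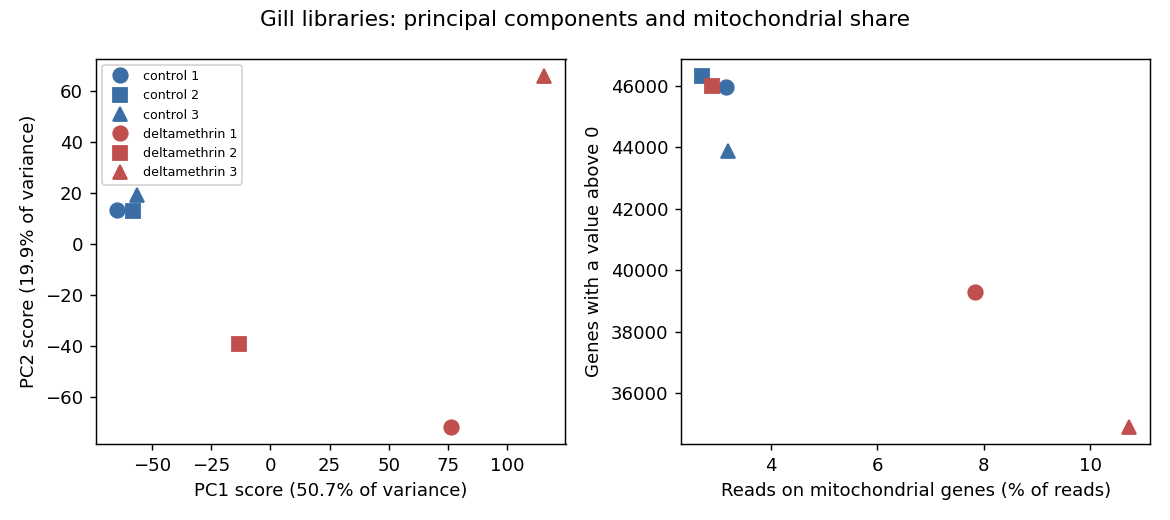
Left, scores of the 6 libraries on the first and second principal components of log2(FPKM + 1) (50.7% and 19.9% of the variance); right, the percent of reads on mitochondrial genes against the number of genes above 0, with blue for control and red for deltamethrin. Deltamethrin library 2 lies near the controls on the right (2.90% and 45981 genes), while libraries 1 and 3 stand apart at 7.84% and 10.7%.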

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

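The total-read scaling, the mitochondrial covariate and the omission of deltamethrin libraries 1 and 3 were chosen after the results were seen; the others were planned. Over all settings, named genes stayed on their side of the threshold in 3271 results, gained the call in 74 and lost it in 627; lists stayed on theirs in 760, gained the call in 8 and lost it in 47, and list medians changed sign in 52 of these, over 14 lists. Among genes past the threshold, the 1 change of sign was krt98 with copies merged (0.60), where other copies are summed with it. Among named genes not past it, the sign changed in 13 of these results, over 6 genes. Leaving out 1 library gave 83 to 5860 changed genes (63 to 2987 higher, 20 to 2873 lower, 83 to 4770 at least 2-fold), 15 to 19 lists, 29 to 42 families, and a gap in mean correlation between control pairs and mixed pairs of 0.0924 to 0.143. A pseudocount of 0.1 left 315 lower genes. No filter gave 322 changed (200 higher, 122 lower, 319 at least 2-fold) of 53880 tested, and 67 families. Array weights gave 3883 (1898 higher, 1985 lower, 3412 at least 2-fold). Merged copies gave 16 families. The covariate gave 461 (323 higher, 138 lower, 461 at least 2-fold) and 57 families. Without deltamethrin libraries 1 and 3, families numbered 59 and the correlation gap 0.0618. There the lone exposed library is assumed to vary like the controls, so its counts of genes and families are not given. The totals of kept, gained and lost calls above include that fit. The estimated correlation left 0 lists. The test fry, which asks whether a list moves one way rather than comparing it with other genes, called 10 lists, of which 9 were among the 17; cartilage and bone markers were added (adjusted p = 0.0193), and cell cycle (0.0715), T cell, macrophage, muscle, oxidative phosphorylation, ribosomal, matrix and heat shock lists were lost. Voom on the recovered reads called 1048 genes, 792 of them among the 1107. Deviations from the group means of same-numbered libraries correlated at -0.03, 0.06 and 0.08, so the numbers were not taken to pair libraries; the replicate block gave 909 genes, 768 of them among the 1107. The cause of these shifts was not tested. At this depth and with 3 libraries per group, 0 of 50 genes simulated at 2-fold were called. The simulation did not vary depth and gave both groups the same spread.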

Other observations

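Of the tests that weigh explanations, those chosen after the result was seen were of a wrong label, of dilution with control tissue, of leukocyte loss (its genes were picked after the data were seen, and antigen presentation was separated from the interferon genes once its result was known), of the mitochondrial covariate, of blood, and of the splits for the count of genes. Gene families grouped by description were tested beyond the fixed lists, and the families named here were picked after their values were seen. Of 329 families, 17 were higher and 20 lower at a camera adjusted p under 0.05, and 0 kept the call with an estimated correlation. With gene copies merged, 16 of the called families kept the call. Which of the families named here were among those 16 is not given. Poly(ADP-ribose) polymerases, many of them interferon-induced in vertebrates, had 6 of 33 members lower and 0 higher (median log2 change -0.95, adjusted p = 8.41e-09; adjusted p = 0.701 with an estimated correlation). The member parp12a had a log2 change of -1.33. CXC chemokines had 3 of 10 lower (median -1.70, adjusted p = 1.47e-04; adjusted p = 0.837 with an estimated correlation), with cxcl11.1 going from 12.4 ± 8.10 to 0.648 ± 0.603 FPKM (mean ± SD, n = 3 per group). Interferon regulatory factors had 5 of 24 lower, among them the abundant irf1b (386 ± 99.2 to 104 ± 16.4 FPKM). Rh ammonium transporters had 3 of 10 lower and 0 higher (median -1.20, adjusted p = 0.00641; adjusted p = 0.814 with an estimated correlation).

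Nicotinamide riboside kinases led the families that were higher besides PDZ and LIM domain proteins, and had 5 of 11 members higher. The median log2 change was 1.89 (camera adjusted p = 2.17e-06, and 0.807 with an estimated correlation). The 4 members with the smallest p all carried the symbol mibp, so they are copies rather than separate genes. A mibp copy went from 34.5 ± 3.39 to 137 ± 13.3 FPKM. Krueppel-like factors had 8 of 36 higher and 0 lower (adjusted p = 1.70e-04), with klf4 going from 11.1 ± 3.95 to 63.3 ± 5.28 FPKM. Thrombospondins had 5 of 11 higher, bone morphogenetic proteins 6 of 18, and PDZ and LIM domain proteins 4 of 19, each with 0 lower. With an estimated correlation the adjusted p was 0.807 for Krueppel-like factors, 0.701 for thrombospondins, 0.832 for bone morphogenetic proteins and 0.701 for PDZ and LIM domain proteins.

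Deltamethrin library 2 lay nearer the controls than the other exposed libraries. Over 5860 genes called without it, its median position was 0.325 of the way from the control mean to the exposed mean. The left-out controls had 0.0202, 0.139 and 0.0654, over 148, 144 and 83 genes called with library 2 among the exposed. The gene sets differ, so these positions cannot judge a wrong label. The share of genes on the exposed side was 73.9% for library 2, inside the 54.7% to 77.1% of those controls. The median of library 2 was 1.31 for the glucocorticoid-responsive list (controls -0.03, 0.11 and -0.03). For the interferon list it was -0.78 (controls -0.09, 0.04 and 0.14). These medians argue against a control library under a wrong label. At equal reads the mean correlation of library 2 with the controls was still 0.0585 above the higher of the other exposed libraries, which argues against depth. It ranked first in all 5 classes of gene length, which argues against length as the whole cause of its nearness. A trend with length was present all the same. The median shift of all genes in the shortest class was -0.117, -0.012 and -0.396 in deltamethrin libraries 1 to 3. In the longest class it was -0.001, -0.011 and 0.072. How far this trend bears on the gene lists was not tested. The median of library 2 exceeded what dilution by its position of 0.325 would give, by more than the largest control shift, in 9 of 16 lists called without it (10 of 17 called with all libraries, the form tried first). That position comes from genes called on libraries 1 and 3, whose quality is open, and may be too low. The count argues against even dilution with control tissue as the whole cause only as far as that position holds. A response or dose that differed by gene group stays open as untested, and so does the quality of libraries 1 and 3, whose mitochondrial shares of 7.84% and 10.7% and 39289 and 34917 genes detected, against 2.90% and 45981 in library 2, go with the pattern.

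Interferon and antigen presentation genes were lower in the exposed gills. In pan-leukocyte genes (43 tested, median log2 change -0.60) the fall was 0.19 smaller than in the interferon list, and the pan-leukocyte median minus the interferon median was 0.222, 0.432 and 0.244 in the exposed libraries against 0.0518, -0.162 and -0.00747 in the controls. That would argue against an even loss of all leukocytes as the whole cause for the interferon genes only if both sets had similar levels. Their levels were not matched, and the log2(FPKM + 1) scale shrinks changes of low genes, so the difference cannot decide this. Nor can the difference speak to the loss of single cell types, whose lists fell unevenly. Their medians were -0.80 for T cell, -0.48 for macrophage, -0.26 for neutrophil and -0.24 for B cell markers. For antigen presentation the difference was -0.00464 (0.00873, -0.0286 and 0.239 in the exposed libraries, -0.203, 0.101 and 0.0673 in the controls). By camera at the preset correlation, both lists stayed lower whichever library was left out (highest adjusted p 3.25e-07) and with the mitochondrial share as covariate (highest 1.95e-06). The interferon median was -0.79 before the covariate and -0.84 after, and -0.78 in library 2. That argues against a single library as the whole cause of either fall, and against the mitochondrial share as the whole cause of the interferon fall. The antigen presentation median went from -0.60 to -0.36 with the covariate. In library 2 it was -0.32, close to the -0.22 of control library 2, so the share cannot be judged for this list. Over all settings camera or fry adjusted p ran from 1.39e-15 to 0.0725 for interferon and antiviral genes and from 6.22e-13 to 0.379 for antigen presentation. Leukocyte loss, of all or of some cell types, stays open as part or whole of the cause of the interferon fall. It also stays open as a cause of the antigen presentation fall. So does library quality for antigen presentation, whose median was -0.32 in library 2 against -0.72 and -0.82 in libraries 1 and 3.

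Erythrocyte list genes were higher in the exposed gills. More blood in the sample cannot be told apart from a change in these genes: the other 33 members shifted by 0.586, 0.699 and 0.765, but summed hemoglobin by 2.61, 1.93 and -0.34, so their mean difference of -0.72 lies within its spread. Reads shared between copies of the same symbol do not account for it by camera at the preset correlation. With such copies summed, the list of erythrocyte markers stayed higher (adjusted p = 1.18e-04). Genes with different symbols were not summed, so reads shared between them stay open. With an estimated correlation and copies apart, the camera adjusted p of the list was 0.327.

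The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05, and in each case 1 split, the real one, was as large. The real split gave 1107 changed genes, 1105 of them at least 2-fold, 17 lists and 37 families, and the highest of the other splits gave 0, 0, 13 and 25.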
